A study of Mus musculus with 8 samples.

How the data were processed

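Gene expression was measured in mouse cells carrying a Nanog-GFP reporter, on 8 one-colour TORAY oligonucleotide arrays in 4 groups of 2: primordial germ cells of embryonic day 11.5 (E11.5 PGC), cells after 3 and 6 days of culture (Day3 and Day6), and embryonic germ (EG) cells. Per the labels, total RNA was purified on silica columns, amplified as aminoallyl aRNA and labelled with Cy5. The labels list the culture medium as Knockout DMEM with 15% serum replacement, LIF and bFGF. They also list 1 µM PD325901 (a MEK inhibitor), 3 µM CHIR99021 (a GSK3 inhibitor) and 250 nM A83-01 (an inhibitor of the Activin and Nodal receptors). The same protocol text stands on every sample, the E11.5 PGC samples included, so it does not say which cells met the inhibitors at harvest. Only the names of the Day3, Day6 and EG samples carry the inhibitors.

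The deposited values are linear spot intensity, scaled by the authors so that the median of each array lies near 20. The background correction, the scaling step and the reason for missing cells are not given in the sources used here. The table held 23473 probes, of which 19524 had a value on all 8 arrays and 74 on none; 11674 cells were missing. Probes with a missing cell were dim on the arrays that measured them (median intensity 1.80, against 27.1 for probes measured on all arrays). Array medians lay between 19.99 and 20.01, so the values were kept without further normalization and converted to log2. Missing values stayed missing. One symbol was given for 16631 probes (16426 different symbols), and 6842 probes had none; 12622 probes carried a current symbol, 3911 older symbols were replaced through synonyms in the mouse gene table, and 98 were kept as the table gives them. No named probe was found for Pou5f1 or Sox2, whose values are therefore not used here.

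Comparisons used limma 3.58.1 in R 4.3.3: a linear model per probe on all 8 arrays and 4 groups, with moderated, two-sided tests and Benjamini-Hochberg adjustment over the probes tested in each comparison, at an adjusted p under 0.05. A probe was tested only where both arrays of both groups had a value. Where both arrays of one group and neither of the other had a value, the intensity is given with no fold and no test, since the reason for the missing values is not stated. A group is described as near the floor where both of its arrays lie under an intensity of 4.24, the limit of the dimmest probes. The array names in the labels fall into 2 series, A (replicate 1 of E11.5 PGC, Day3 and Day6, and both EG arrays) and B (replicate 2 of E11.5 PGC, Day3 and Day6). The model had no term for this series. A model with the array series as a block is reported beside it, and so are changes within each series. For EG, which has arrays in series A only, blocked values rest on the assumption that the series difference is the same in every group.

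The rule for named genes, the gene lists and the settings to be tried were fixed before the data were examined. For each comparison the rule names the 8 genes with the highest and the 8 with the lowest change among called probes whose arrays did not overlap between groups, 2 to 4 members of each list described, and 20 marker genes. Where a gene had several probes the brightest was used. The same rule applied to the blocked model, comparison Day6 against E11.5 PGC, the fit on series A alone, changes within each series, list medians without each array, and blocked models with a second setting were added after the data were seen. The 23 lists were core pluripotency, naive pluripotency regulators, primed epiblast, early germ cell, later germ cell, meiosis, MEK/ERK targets, Wnt targets, TGF-beta/Activin targets, LIF/STAT3 targets, cell cycle, CDK inhibitors with p53 targets, glycolysis, oxidative phosphorylation, DNA methylation, imprinted genes, epithelial adhesion, gonadal somatic cells, fibroblast/mesenchyme, endothelium, blood, extraembryonic tissue, and immediate early/stress genes. Some genes stand in more than 1 list. Each list was tested with limma camera with a preset correlation of 0.01, which compares its genes with all others, with camera with an estimated correlation, and with fry, which tests whether its genes move one way on balance. Adjustment ran over the 92 tests of 23 lists in 4 comparisons. Missing values were set to the lowest value of the array in these list tests only. A list median is the median log2 change of its tested members.

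A transcript was called transient at a culture day when it was higher, or lower, than both E11.5 PGC and EG at that threshold. The position of a cultured array between E11.5 PGC and EG is the slope of its change from E11.5 PGC on the change from E11.5 PGC to EG. Each axis used arrays of a different replicate number, and the slope was divided by the slope of the EG changes of the 2 numbers on each other.

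Alternatives were quantile normalization, centring on the median of probes measured on all arrays, a pseudocount of 2.275, removal of the 5850 dimmest probes (intensity under 4.24), missing values at the lowest value of the array, only probes measured on all arrays, the replicate number or the array series as a block, only the arrays of the groups compared, trend and robust variance, and each array left out in turn. Where a group is left with 1 array, that array is assumed to vary like the others. The tests were checked on simulated data with 2 arrays per group, in which 200 of 19524 probes were changed at Day3. Without a series difference, the model without a block recovered 93.4% of 4-fold and 22.2% of 2-fold changes. With a series difference as measured it recovered 0% of either, and the model with the array series as a block recovered 95.1% and 14.4%. False calls were 8.21% of the calls of this blocked fit, and 7.06% and 6.4% with and without the block where there was no series difference, all above the 5% aimed at. The simulated series difference was itself an estimate from these arrays. With so few changed probes the adjusted threshold is strict, so the recovery rates do not carry over to the measured data. There the model without a block called 431 probes for Day3 over E11.5 PGC. With 2 arrays in each group, the number of arrays limits the precision. The labels do not say whether the 2 arrays of a group come from separate animals or cultures, so p-values measure only the spread between these samples. Tables and figures were made with python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.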

Results

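The arrays cover mouse primordial germ cells of stage E11.5, the embryonic precursors of eggs and sperm, and cells after 3 and 6 days of culture. They also cover embryonic germ cells, a pluripotent line derived from germ cells. Each of the 4 groups has 2 arrays. Between 21126 and 22404 of the 23473 probes had a value on each array, and the array medians of the scaled intensity lay between 19.99 and 20.01. Nanog, a core pluripotency factor and the gene of the reporter, was bright in every group: its intensity was 1520 and 1707 in E11.5 PGC, 2671 and 4321 at Day3, 4294 and 8992 at Day6, and 2422 and 4183 in EG.

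The 8 arrays spread along a first principal component with 44.1% of the variance, on which E11.5 PGC scored -66.7 and -100.6, Day3 10.3 and -32.1, Day6 67.2 and 1.06, and EG 57.6 and 63.2. On the third component (14.9%), EG scored 42.65 and 44.57, and replicate 1 of Day3 and Day6 -52.52 and -49.39. Deviations of replicate 1 from its group mean were correlated across probes between E11.5 PGC and Day3 (r = 0.62), E11.5 PGC and Day6 (0.547) and Day3 and Day6 (0.694), whose replicates 1 and 2 lie in array series A and B. They were not with EG, both of whose arrays lie in series A (r = -0.025, 0.005 and 0.061). These correlations are across 19524 probes, which are not independent replicates.

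**Figure D1:**
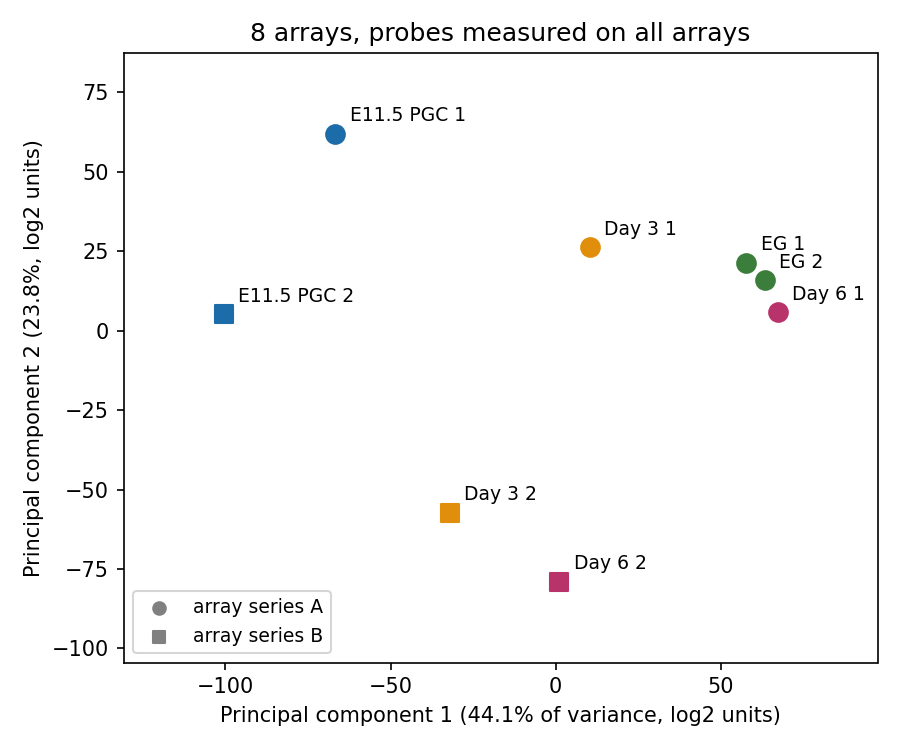
Scores of the 8 arrays on the first principal components of log2 intensity, with colours for groups and circles or squares for array series A or B. EG replicates 1 and 2 score 57.6 and 63.2 on component 1, near Day6 replicate 1 at 67.2. On component 3, which is not drawn, they score 42.65 and 44.57, far from Day6 replicate 1 at -49.39.

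Day3 was compared with E11.5 PGC to ask what changes first when germ cells enter culture. Klf4, a transcription factor of naive pluripotency, rose by 2.40 ± 0.32 on the log2 scale (standard error, n = 2 arrays per group), from a geometric mean intensity of 52.5 to 276. Fgf4, a growth factor made by pluripotent cells, rose by 4.01 ± 0.50 (3.05 with a pseudocount, as its level in E11.5 PGC was near the floor), and Dnmt3b, a de novo DNA methyltransferase, by 3.11 ± 0.41. Lhx1, a LIM homeobox gene, fell by 6.39 ± 0.36, from an intensity of 414 to 4.95, and Lefty1, a secreted inhibitor and target of Nodal signalling, fell by 4.58 ± 0.35. The changes of Klf4 were 2.55 in series A and 2.25 in series B, those of Fgf4 3.58 and 4.44, and those of Lhx1 -6.78 and -6.00.

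The list of CDK inhibitors and p53 target genes had the lowest p at Day3: 4 of its 16 tested members rose, 0 fell and 12 gave no call; adjusted over the list alone, 10 rose and 1 fell. Phlda3 rose by 4.27 ± 0.41, Ccng1 by 3.65 ± 0.25, Zmat3 by 2.00 ± 0.36 and the death receptor gene Fas by 1.96 ± 0.27. The list median was 1.23 (1.15 in series A and 1.21 in series B), with a camera adjusted p of 1.21e-07 and a fry adjusted p of 0.0119; adjusted p = 0.416 with an estimated correlation. Cdkn1a, the p21 gene and best known p53 target, changed by 2.53 ± 0.49 with an adjusted p of 0.0526, and rose with the array series as a block (adjusted p = 0.00338).

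Of the 14 core pluripotency genes tested, 2 rose (Fgf4 and Fbxo15, the latter by 2.73 ± 0.41) and 0 fell; adjusted over the list alone, 7 rose and 1 fell. Of 19 naive regulators, 3 rose, namely Tbx3 by 3.70 ± 0.66, Klf4, and Stat3, the transcription factor downstream of LIF, by 1.98 ± 0.28, and 0 fell (6 and 1 adjusted over the list alone). Klf4 and Stat3 were also the 2 of 14 LIF/STAT3 targets that rose, with 0 that fell (4 and 0 adjusted over the list alone). The list medians were 0.85, 0.36 and 0.38, and the camera adjusted p was 0.00766, 0.0012 and 0.0031. With an estimated correlation each had an adjusted p = 0.416, and fry gave 0.0336 (0.105 with the block), 0.0432 and 0.0127. The naive median was 0.11 and 0.68 without E11.5 PGC replicate 1 and 2, and 0.86 and 0.06 without Day3 replicate 1 and 2. Nanog changed by 1.08 ± 0.46 (adjusted p = 0.354) and Zfp42 (Rex1), a marker of naive cells, by 1.21 ± 0.30 (adjusted p = 0.109), neither of them a call. Zfp42 rose with the array series as a block (adjusted p = 0.0221), where Nanog gave no call (0.101). Esrrb changed by 0.155 ± 0.626 and Tfcp2l1 by 0.395 ± 0.704, without a call in either model. Klf2 changed by 1.005 ± 0.247 (adjusted p = 0.107) and rose with the block (0.0303).

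Camera called both germ cell lists downward at Day3, and fry neither (adjusted p = 0.0579 for the early and 0.0797 for the later list). Of 17 early germ cell genes 3 fell and 0 rose, the same counts as adjusted over the list alone: Lhx1, Cxcr4, the receptor that guides migrating germ cells, by 2.52 ± 0.46, and the RNA-binding protein gene Dnd1 (-2.17). For this list the median was -0.42 (-0.23 without Day3 replicate 2) and the camera adjusted p 0.0275; adjusted p = 0.450 with an estimated correlation, and 0.0743 with the array series as a block, which ends the call. Of 23 later germ cell genes 0 passed the threshold, although 5 fell adjusted over the list alone. Their median was -0.81 (-0.80 in series A and -0.40 in series B; -0.41 without E11.5 PGC replicate 1 and -0.53 without Day3 replicate 1), with a camera adjusted p of 0.00627 and an adjusted p = 0.450 with an estimated correlation. With the array series as a block 7 fell, among them Asz1 (-3.05), Tdrkh (-1.93), Mael (-1.74) and the germ cell helicase gene Ddx4 (-1.34), and the camera adjusted p was 0.00607. Dppa3, a maternal and germ cell factor also called Stella, changed by -0.75 ± 0.67 and Dazl, a germ cell RNA-binding protein gene, by -0.47 ± 0.86, without a call.

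Epithelial adhesion genes were called upward (median 0.17; camera adjusted p = 0.0143; adjusted p = 0.495 with an estimated correlation; fry 0.142), with 2 of 15 members that rose, Spint1 by 3.12 ± 0.47 and Cldn6 by 2.43 ± 0.34, and 0 that fell (4 and 1 adjusted over the list alone). Their median was 0.51 without E11.5 PGC replicate 2, and 0.50 and 0.31 without Day3 replicate 1 and 2. Among markers of other cell types, the fibroblast/mesenchyme list was called upward (camera adjusted p = 0.0118; adjusted p = 0.604 with an estimated correlation; fry 0.514). Dcn, a matrix proteoglycan gene, was the 1 of its 19 members that rose, by 4.22 ± 0.76, and the list median was 0.26 (0.79 in series A and 0.06 in series B; 0.39 without E11.5 PGC replicate 2, and 0.10 and 0.71 without Day3 replicate 1 and 2). The other 15 lists were not called by camera (adjusted p from 0.0612 to 0.793). Imprinted genes split, with Igf2 falling by 3.37 ± 0.59 and Sgce rising by 2.95 ± 0.53 among 20. In primed epiblast genes Dnmt3b and Cldn6 rose and Lefty1 fell among 14, and in TGF-beta/Activin targets Lefty1 and Skil (-2.88) fell and Cyr61 (2.36) rose among 15. Meiosis (Spo11 -2.91, near the floor at Day3, and Stag3 -1.52), glycolysis (Slc2a3 2.02, and Hk2), gonadal somatic cells (Pax8 -2.00), endothelium (Cldn5 -2.96), blood (Tyrobp -1.71) and DNA methylation (Dnmt3b) each had 1 or 2 called members, and MEK/ERK targets, Wnt targets, cell cycle, oxidative phosphorylation, extraembryonic and immediate early/stress genes had 0. The direction from camera was upward against a negative median for DNA methylation (median -0.18, mean 0.52), extraembryonic genes (-0.21 and 0.08) and glycolysis (-0.13 and -0.06).

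Fry called the DNA methylation list at Day3 as well (adjusted p = 0.0318, upward), and camera did not (0.0612; adjusted p = 0.431 with an estimated correlation). Its members moved both ways, and its median was -0.18, but -0.10 and 0.00 without E11.5 PGC replicate 1 and 2, and 0.00 and 0.07 without Day3 replicate 1 and 2. Endothelium was the other list called by fry and not by camera, downward with a fry adjusted p just under 0.05 (0.139 with the block, which ends the call; camera 0.365; adjusted p = 0.604 with an estimated correlation). Its median was -0.41, but -0.23 without E11.5 PGC replicate 1 and -0.11 without Day3 replicate 2.

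The called genes with the highest computed changes at Day3 were Anxa8 (5.74 ± 0.64; intensity 158 and 44.2, against 2.19 and 1.11 in E11.5 PGC), the creatine transporter gene Slc6a8 (5.27), the fatty acid binding protein gene Fabp3 (4.88), Bcat1, an enzyme of branched-chain amino acid metabolism (4.83), the aquaporin gene Aqp3 (4.76), the acute-phase gene Saa3 (4.69), Nupr1 (4.61) and Klf9 (4.57). Besides Lhx1 and Lefty1, the lowest were Umodl1 (-4.74), Enpp2, which encodes autotaxin (-4.73), Mogat2 (-4.22), Mkx (-4.19), Klk8 (-4.18) and Ptpre (-4.17). Sizes and ranks are not exact where one group lies near the floor of the arrays, as for Anxa8, Saa3 and Tm4sf1 in E11.5 PGC and Enpp2, Klk8 and Umodl1 at Day3. With a pseudocount the changes were 4.47 for Anxa8, 3.96 for Saa3, -3.27 for Klk8 and -4.09 for Umodl1. Nupr1 had E11.5 PGC intensities of 4.27 and 1.61 and changed by 3.10 in series A and 6.12 in series B. Its size and rank are therefore not exact either. Genes among the 8 highest with the array series as a block, and not called without it, were Ankrd1 (6.38), Tm4sf1 (5.84), B2m, the light chain of class I major histocompatibility molecules (5.52), Anxa1 (5.48), Ly6c1 (5.24) and Efemp1 (5.01). At Day6 each was brighter on replicate 1 than on replicate 2, as for Ankrd1 (445 and 3.97), Tm4sf1 (706 and 6.21) and B2m (3942 and 191). Ankrd1 had intensities of 5.71 and 1.01 in E11.5 PGC, so its size and rank are not exact.

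In total 431 of 20678 probes were called between Day3 and E11.5 PGC, 275 higher and 156 lower. The median change of all probes was -0.13. The model with the array series as a block called 1725, 898 higher and 827 lower. The count rests on single arrays: it was 29 and 4 without E11.5 PGC replicate 1 and 2 (20 higher and 9 lower, and 0 and 4), 90 and 83 without Day3 replicate 1 and 2, and 144 without either EG array. With the block it was 507, 131, 93 and 935 without E11.5 PGC replicate 1, Day3 replicate 1, Day3 replicate 2 and either EG array, and 604 without E11.5 PGC replicate 2. It was 67 with the 4 arrays of these groups alone.

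**Figure D2:**
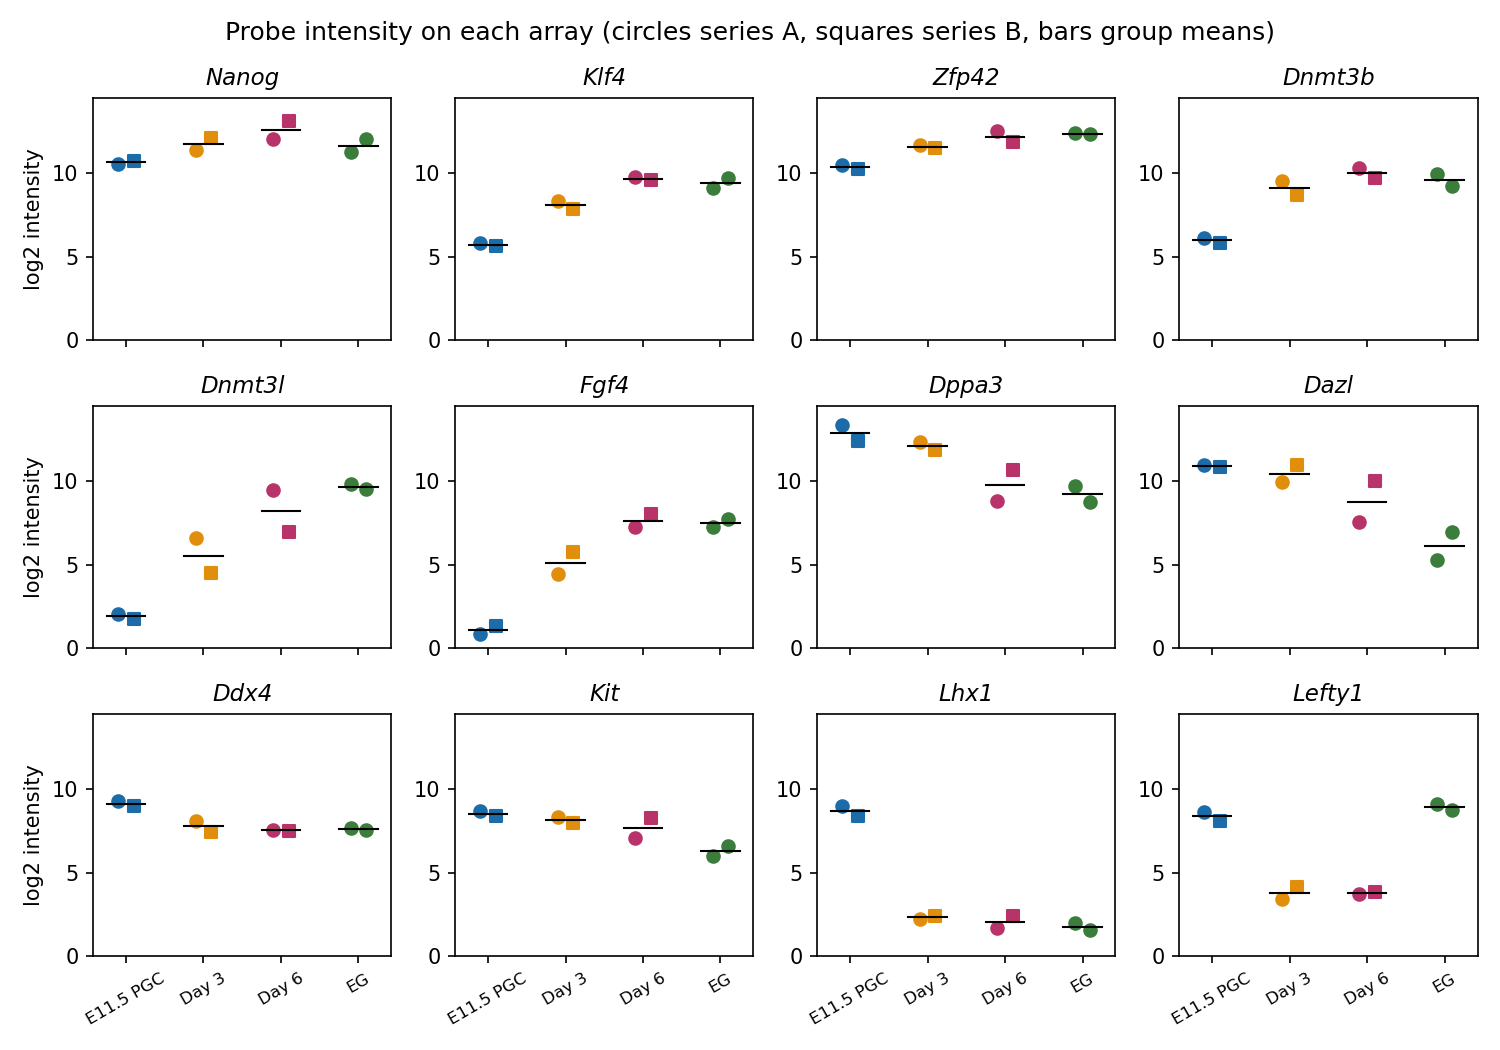
Log2 probe intensity of 12 named genes on each array in the 4 groups, with circles for array series A, squares for series B and bars for group means. Klf4 goes from intensities of 55.9 and 49.2 in E11.5 PGC to 550 and 846 in EG, and Lhx1 from 513 and 335 to 3.87 and 3.00.

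Day6 was compared with Day3 to follow the second part of the culture period. With the array series as a block, Dnd1 fell by 3.48 ± 0.22 (standard error, n = 2 arrays per group) and the X-linked homeobox gene Rhox6 by 4.56 ± 0.59, both expressed in germ cells. In that model the epithelial splicing regulator Esrp1 fell by 3.98 ± 0.54 and the imprinted RNA gene H19 by 3.33 ± 0.50, to a level near the floor, while Fgf4 rose by 2.52 ± 0.28, Tbx3 by 1.87 ± 0.22 and Klf4 by 1.56 ± 0.26. The changes of Dnd1 were -3.72 in series A and -3.23 in series B, those of Klf4 1.40 and 1.73. Without the block limma called 0 of 20015 probes at the same settings, and 1783 had an unadjusted p under 0.05.

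Members of the lists gave no call without the block, but 7 lists were called. Later germ cell genes (median -0.36; camera adjusted p = 0.0012) and meiosis genes (-0.61; 0.0012) were called downward at Day6, each with an adjusted p = 0.450 with an estimated correlation. Early germ cell genes (median -0.47; camera adjusted p = 0.0118) also were, with an adjusted p = 0.450 with an estimated correlation. Their median was -1.26 in series A and -0.01 in series B, and -0.08 and -1.04 without Day6 replicate 1 and 2. Without Day3 replicate 2 the later germ cell median was -0.58 and the meiosis median -0.32, and without Day6 replicate 1 the latter was -0.20. Adjusted over the list alone, 4 of 23, 1 of 19 and 2 of 17 fell and 0 rose. With the block Tdrd5 (-2.41), Dmrt1 (-2.31), Tdrkh (-2.21), the cohesin gene Stag3 (-1.65), Rhox6 and Dnd1 fell. Epithelial adhesion genes were called downward, with a median of -0.09 and a mean of -0.86 (camera adjusted p = 0.0143; adjusted p = 0.495 with an estimated correlation; 0.0608 with the block, which ends the call). Their median was -0.31 without either Day3 array, and -0.05 and -0.47 without Day6 replicate 1 and 2. Adjusted over the list alone 5 of 15 fell and 0 rose, and with the block Esrp1, Cldn6 (-2.90), the desmosome gene Dsp (-2.64) and Epcam (-1.69) fell.

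Core pluripotency genes (median 0.43; camera adjusted p = 0.0347) and naive regulators (0.20; 0.0143) were called upward, with an adjusted p = 0.450 and 0.416 with an estimated correlation. Adjusted over the list alone 3 of 14 rose and 0 fell, and 5 of 20 rose and 1 fell. The core median was 0.21 without Day3 replicate 2, and the naive median 0.31 without Day3 replicate 1 and 0.45 without Day6 replicate 1. Within series A and B the core median was 0.05 and 0.56 and the naive median 0.12 and 0.42, so these shifts lie mostly in series B. The KRAB zinc finger gene Zfp57, which protects imprints, rose by 2.18 ± 0.26 with the block. Immediate early/stress genes were called downward (median -0.51; camera adjusted p = 0.0347; adjusted p = 0.431 with an estimated correlation; median -0.30 without Day6 replicate 2), with 0 of 14 members called in either model. Camera gave adjusted p-values from 0.061 to 0.795 for the other 16 lists, and fry without the block gave no list an adjusted p under 0.05. Median and mean had opposite signs for Wnt targets (0.09 and -0.26), imprinted genes (0.08 and -0.23), gonadal somatic cells (0.03 and -0.11), endothelium (-0.07 and 0.09) and oxidative phosphorylation (-0.01 and 0.04). With the block the DNA methylation list had a camera adjusted p of 0.0272, a fry adjusted p of 0.0295, and adjusted p = 0.749 with an estimated correlation. Its median was 0.17, but 0.07 without Day3 replicate 1 and 0.37 without Day6 replicate 1. In that model Uhrf1, the partner of the maintenance methyltransferase, rose by 1.91 ± 0.22. The fibroblast/mesenchyme list had a median of 0.97 in series A and -0.24 in series B (camera adjusted p = 0.257). Its member S100a4 had a log2 intensity of 10.38 in Day6 replicate 1 and 3.72 in Day6 replicate 2, and Acta2 one of 7.63 and 2.62.

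With the block, the 8 genes highest at Day6 over Day3 were Stk33 (4.40), Adcy2 (4.31), Armcx1 (4.18), Crygf (4.01), Ttn (3.88), Armcx2 (3.79), Pdcl2 (3.73) and the lysosomal gene Laptm5 (3.69). A second probe for Ttn changed by 1.07 without a call (adjusted p = 0.0765 with the block), and both probes lay near the floor at Day3, so the size and rank of this change are not exact. The 8 lowest were Rhox6, Pax6 (-4.25), Esrp1, Dnd1, H19, Cpeb1 (-3.23), Isl2 (-3.21) and Zfp521 (-3.05), where the sizes and ranks of H19 and Zfp521 are not exact either, as both lay near the floor at Day6. Of the 20 marker genes Dppa3 changed by -2.36 ± 0.67 (adjusted p = 0.284; -3.51 in series A and -1.21 in series B) and Nanog by 0.87 ± 0.46 (adjusted p = 0.702). The blocked model called 361 probes, 195 higher and 166 lower. Without one array of these groups the blocked count was 0 for either Day3 array, 0 and 1 for Day6 replicate 1 and 2, and it was 96 without either EG array. Without the block, other settings gave 62 probes with a pseudocount, 34 with trend and robust variance, and 0 with quantile normalization, without the dimmest probes or without any 1 array.

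EG cells were compared with Day6 to see what still separates cultured cells from an established pluripotent line. H19 was higher in EG by 5.56 ± 0.57 (standard error, n = 2 arrays per group; intensity 150 and 201, against 3.70 and 3.67, which is near the floor; 4.88 with a pseudocount), and Lefty1 by 5.17 ± 0.35 (551 and 435, against 13.2 and 14.0). Spic, an Ets family transcription factor, was lower by -5.84 ± 0.63, and Plagl1, an imprinted zinc finger gene, by -4.28 ± 0.48. The endothelial guidance receptor gene Robo4 rose by 3.27 ± 0.32. With the array series as a block the changes were 5.26 for H19, 5.20 for Lefty1, -5.82 for Spic and -4.52 for Plagl1, and within series A they were 5.55, 5.21, -5.66 and -4.25; no EG array lies in series B.

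Glycolysis genes were called upward as a list in EG over Day6 (median 0.96; 0.61 with the block and 0.44 in series A; camera adjusted p = 4.39e-06; fry 0.116), with an adjusted p = 0.450 with an estimated correlation. Of 20 members 0 passed alone and 3 rose adjusted over the list alone. With the block the lactate exporter gene Slc16a3 rose by 3.49 ± 0.48 and the aldolase gene Aldoc by 2.15 ± 0.35. The list median was 1.54 and 0.44 without Day6 replicate 1 and 2. Epithelial adhesion genes (median 0.29, and 0.48 without Day6 replicate 2; camera adjusted p = 0.00766; adjusted p = 0.465 with an estimated correlation) had 0 of 15 called members and 3 that rose adjusted over the list alone; with the block Esrp1 rose by 3.38 ± 0.58 and Epcam by 1.73 ± 0.30. Endothelium genes (median 0.47; camera adjusted p = 0.0275; adjusted p = 0.416 with an estimated correlation; 0.0793 with the block, which ends the call; fry 0.0218, and 0.105 with the block) had 1 of 13, Robo4, that rose and 0 that fell, and 4 and 0 adjusted over the list alone. H19 rose and Plagl1 fell among 20 imprinted genes, and Lefty1 was the 1 called member of the primed epiblast and of the TGF-beta/Activin lists. None of the members of the other lists was called without the block, and their camera adjusted p-values lay between 0.061 and 0.975. The median of CDK inhibitors and p53 targets was -0.23 and the mean 0.08, and the median of MEK/ERK targets was 0.29, but -0.16 with the block. The fibroblast/mesenchyme median was -0.50 (-1.77 in series A; -0.05 and -1.77 without Day6 replicate 1 and 2; camera adjusted p = 0.061). With the block it was -0.92 and the list was called downward (camera adjusted p = 0.0364), with an adjusted p = 0.775 with an estimated correlation and 0 called members.

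The other genes with the highest change from Day6 to EG were Nphs1 (4.44), Patl2 (4.23), the neuronal filament gene Prph (3.84), Duxbl1 (3.62), and the transporter genes Slc7a7 (3.31) and Slc46a3 (3.30). Rab38 (-3.04) and Ppp2r2c (-2.52) were the other named genes with a lower level. Klf4 changed by -0.26 ± 0.32 (adjusted p = 0.814), Zfp42 by 0.18 ± 0.30 (0.868), Nanog by -0.97 ± 0.46 (0.448), Dppa3 by -0.54 ± 0.67 (0.813) and Dazl by -2.65 ± 0.86 (0.259), none of them a call. In total 34 of 20103 probes were called, 28 higher and 6 lower. The count was 395 (251 and 144; 239 and 244 with centring as well) with the array series as a block and 0 within series A, where Day6 has 1 array. It was 2 without either E11.5 PGC array, 6 without either Day3 array, and 0 without either Day6 or either EG array. With the block it was 4 without either Day3 array, 0 without either Day6 array, and 19 and 18 without EG replicate 1 and 2.

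EG cells were compared with E11.5 PGC to give the distance between the uncultured germ cells and the established line. Dnmt3l, a cofactor of de novo DNA methylation, was higher by 7.76 ± 0.91 (standard error, n = 2 arrays per group; intensity 902 and 739, against 4.20 and 3.38) and Fgf4 by 6.40 ± 0.50. Both lay near the floor in E11.5 PGC, and with a pseudocount the changes were 7.08 and 5.36. Klf4 rose by 3.70 ± 0.32, Zfp42 by 2.00 ± 0.30 and Dnmt3b by 3.60 ± 0.41. Of germ cell genes, Asz1, which acts in the piRNA pathway, fell by 6.38 ± 0.73, Dazl by 4.80 ± 0.86, Dppa3 by 3.64 ± 0.67 and the stem cell factor receptor gene Kit by 2.22 ± 0.45. With the array series as a block these changes were 6.93 for Dnmt3l, 6.82 for Fgf4, 3.57 for Klf4, -6.02 for Asz1 and -4.25 for Dazl, and within series A they were 7.60, 6.62, 3.61, -6.69 and -4.86.

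Of 23 later germ cell genes 9 fell, 0 rose and 14 gave no call, and 16 fell adjusted over the list alone; besides Asz1 and Dazl these included Stk31 (-3.02), Tdrkh (-2.99) and Ddx4 (-1.51). The list median was -1.51 (-1.56 in series A), with a camera adjusted p of 5.8e-05, a fry adjusted p of 0.0198 (0.0522 with the block, which ends the fry call), and an adjusted p = 0.418 with an estimated correlation. Of 17 early germ cell genes 6 fell and 0 rose (8 and 2 adjusted over the list alone): Lhx1 (-6.93), Dnd1 (-4.24), Dppa3, Cxcr4 (-2.98), Kit and Hmgb3 (-1.99). Their median was -1.33 (-1.78 with the block; -0.87 without EG replicate 2) and the camera adjusted p 0.0147; adjusted p = 0.450 with an estimated correlation, and 0.0658 with the block, which ends the call, while the fry adjusted p was 0.0127. Nanos3, Prdm1, Prdm14 and Tfap2c, other members of the early germ cell list, changed by -1.57, -0.16, -0.14 and -0.74 without a call. Mael changed by 0.07 ± 0.49 (adjusted p = 0.952).

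Of 14 core pluripotency genes 5 rose and 0 fell (7 and 1 adjusted over the list alone): Fgf4, Eras, a Ras family gene of pluripotent cells (6.39), the Nodal co-receptor gene Tdgf1 (5.35), Zfp42 and Fbxo15 (1.91). Of 19 naive regulators 6 rose (Tbx3 4.65, Nr0b1 4.46, Manba 4.22, Jam2 3.98, Klf4 and Stat3 1.72) and Pecam1 fell by 2.35 ± 0.54. Adjusted over the list alone 8 rose and 2 fell. The other 12 gave no call, the naive markers Esrrb, Tfcp2l1 and Klf2 among them. Their geometric mean intensities in E11.5 PGC and EG were 11.2 and 19.9 for Esrrb, 19.6 and 10 for Tfcp2l1, and 173 and 223 for Klf2. The LIF/STAT3 list had 3 of 14 that rose, Klf4, Stat3 and Pim3 (1.34), and 0 that fell (4 and 0 adjusted over the list alone). The medians were 0.94, 0.67 (0.38 with the block, and 0.36 without E11.5 PGC replicate 1) and 0.62 and the camera adjusted p 0.00298, 0.0012 and 0.00766; each had an adjusted p = 0.416 with an estimated correlation and a fry adjusted p of 0.0119. Nanog changed by 0.98 ± 0.46 (adjusted p = 0.226), and by 1.30 ± 0.36 with the block, where it passed (adjusted p = 0.0447).

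CDK inhibitors and p53 targets were called upward as a list in EG as well (median 1.22; camera adjusted p = 0.000543; fry 0.0127; adjusted p = 0.416 with an estimated correlation), with 5 of 15 that rose, Ccng1 (3.57), Phlda3 (3.54), Zmat3 (3.02), Perp (1.98) and Fas (1.22), and Cdkn1c, an imprinted CDK inhibitor gene, that fell by 2.48 ± 0.61; adjusted over the list alone 8 rose and 1 fell. Glycolysis genes had 4 of 20 that rose and 0 that fell: the glucose transporter genes Slc2a3 (2.96) and Slc2a1 (2.56), Slc16a3 (2.72) and the hexokinase gene Hk2 (2.41). Adjusted over the list alone 8 rose. Their median was 1.36 (1.17 in series A), with a camera adjusted p of 1.34e-05, an adjusted p = 0.450 with an estimated correlation, and a fry adjusted p of 0.0723.

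The remaining 16 lists were not called by camera between EG and E11.5 PGC without the block (adjusted p from 0.0589 to 0.927). DNA methylation genes had 4 of 17 that rose (Dnmt3l, Uhrf1 3.73, Dnmt3b and Apobec1 2.25) and 2 that fell (Mbd3 -2.06 and Tet3 -1.39), with a fry adjusted p of 0.0119, a camera adjusted p of 0.124 and an adjusted p = 0.450 with an estimated correlation. Their median was 0.37, but -0.13 with the block and -0.22 without either E11.5 PGC array, so it gives no direction. Imprinted genes had 3 of 20 that rose (Sgce 4.52, Meg3 2.60 and Impact 2.32) and 4 that fell (Igf2 -3.94, Peg3 -3.07, Cdkn1c and Usp29 -2.33); the list mean was -0.28 and the direction from camera upward (adjusted p = 0.927). Primed epiblast genes had 2 that rose (Dnmt3b and Nodal 1.76) and Fgf5 (-2.84) that fell, and TGF-beta/Activin targets had 3 that rose (Pmepa1 2.99, Nodal and Cyr61 1.28) and Skil (-2.17) that fell. Called members of the other lists were Spint1 (3.90), Perp and Ocln (1.63) up and Esrp1 (-2.69) and Dsp (-1.90) down for epithelial adhesion, Stag3 (-1.42) and Tex15 (-1.28) for meiosis, Spred1 (-2.60) for MEK/ERK targets, Lef1 (-3.15) for Wnt targets, and Mcm6 (-1.34) for the cell cycle, where 8 of 24 fell with the block. Atp5o (-1.17) and Cycs (-1.09) were the called members for oxidative phosphorylation. With the block 6 of 24 fell and the list was called downward (median -0.56; camera adjusted p = 0.0487), with an adjusted p = 0.807 with an estimated correlation. The called member was Dnajb1 (-1.59) for immediate early/stress genes. Among markers of other cell types, Gata2 (-3.10) and Pax8 (-2.02) fell for gonadal somatic cells, Robo4 (3.86) and Egfl7 (1.44) rose and Cldn5 (-2.84) fell for endothelium, Laptm5 (4.57) and Cd68 (2.10) rose and Tyrobp (-1.84) fell for blood, Lama1 (1.44) rose and Tfap2a (-1.61) fell for extraembryonic genes, and 0 of 18 fibroblast/mesenchyme genes were called. Tet3, Fgf5 and Tfap2a lay near the floor in EG, so the sizes of these changes are not exact. Median and mean had opposite signs for endothelium (-0.06 and 0.34) and blood (-0.18 and 0.31), and for immediate early/stress genes the median was -0.05 with an upward direction from camera.

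Among called genes Zscan4c had the highest computed change (10.11 ± 1.10; intensity 1368 and 4256, against 2.79 and 1.71, which is near the floor; 9.07 with a pseudocount). It belongs to a family of nearly identical genes, so the probe may not tell its members apart. The next were Dnmt3l, the uridine phosphorylase gene Upp1 (7.45), Nupr1 (7.22), the oocyte homeobox gene Obox1 (7.06), Patl2 (7.04), Fez1 (6.82) and Fgf4. Dnmt3l, Obox1, Patl2, Fez1 and Fgf4 also lay near the floor in E11.5 PGC, and Lhx1 in EG, so that their sizes and ranks are not exact (with a pseudocount 5.84 for Obox1 and 5.71 for Fez1). The same holds for Nupr1, whose E11.5 PGC intensities were 4.27 and 1.61. Besides Lhx1, Asz1 and Dazl, the lowest were Mogat2 (-5.47), Nlrp4c (-5.16), the homeobox gene Msx2 (-5.11), Ap3b2 (-5.10) and Runx1t1 (-5.08). In total 2321 of 20761 probes were called, 1157 higher and 1164 lower. The array series as a block gave 4905 (1919 and 2986), a split that turned to 2117 and 1950 with quantile normalization as well. The median change of all probes was -0.16. The count was 652 (445 higher and 207 lower) and 372 (251 and 121) without E11.5 PGC replicate 1 and 2, and 323 (243 and 80) and 232 (169 and 63) without EG replicate 1 and 2. With the block it was 1543 (926 and 617) without E11.5 PGC replicate 1, and 2118 (1051 and 1067) and 1756 (845 and 911) without EG replicate 1 and 2.

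**Figure D3:**
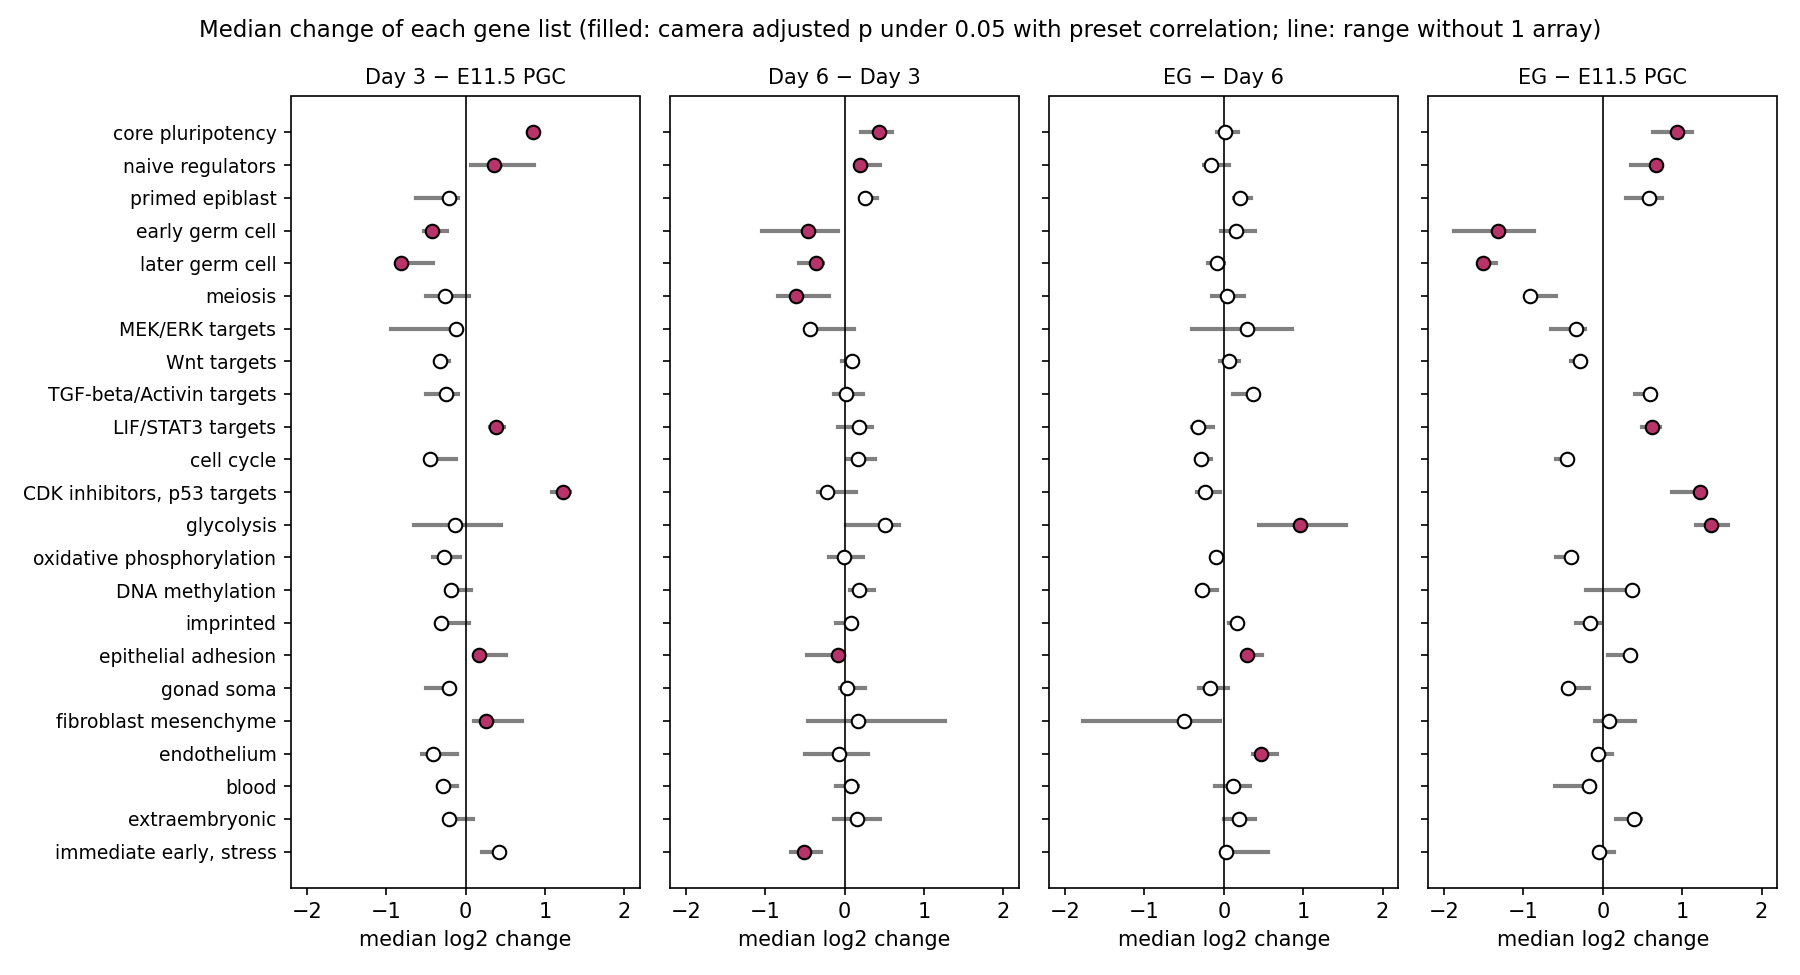
Median log2 change of the 23 gene lists in the 4 comparisons, filled where the camera adjusted p with the preset correlation was under 0.05, with a line for the range when 1 array is left out. CDK inhibitors with p53 targets have a median of 1.23 at Day3 over E11.5 PGC and of 1.22 in EG over E11.5 PGC.

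Some transcripts left the range between E11.5 PGC and EG during culture. At Day3, Lefty1 was lower than in E11.5 PGC (-4.58) and than in EG (-5.16), and so were the protease gene Klk8 (-4.18 and -4.25), Nphs1 (-3.93 and -6.17) and Duxbl1 (-3.92 and -3.98), Gtf2a1l (-2.01 and -2.12) and Csrp2 (-1.59 and -1.93). Spic was higher than both (3.97 and 4.60), as were Mal (3.93 and 4.18), the small GTPase gene Rab20 (4.33 and 3.25), Hsh2d (3.44 and 2.91), Mlkl, the effector of necroptosis (2.67 and 2.88), Fcgr3 (2.24 and 2.66), Trim50 (2.82 and 2.13) and Cldn6 (2.43 and 2.04). At Day6, Spic was again higher (5.20 and 5.84), with Plagl1 (3.33 and 4.28), Rab38 (2.52 and 3.04) and Ppp2r2c (3.76 and 2.52). H19 was lower (-5.28 and -5.56), with Lefty1 (-4.59 and -5.17), Duxbl1 (-3.56 and -3.62), Slc7a7 (-3.16 and -3.31), Enpp3 (-4.89 and -2.96), Prtn3 (-2.86 and -3.29), Cracr2b (-2.86 and -2.94) and Slc46a3 (-2.76 and -3.30). Sizes are not exact for Klk8 and Gtf2a1l, near the floor at Day3, for H19, Prtn3 and Cracr2b, near it at Day6, and for Mal, Hsh2d, Mlkl and Trim50, near it in E11.5 PGC.

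In total 23 probes were called transient at Day3, 13 higher and 10 lower, and 20 at Day6, 5 higher and 15 lower. With the array series as a block there were 153 and 186. The Day3 count was 4 and 1 without E11.5 PGC replicate 1 and 2, 0 and 6 without Day3 replicate 1 and 2, 46 without either Day6 array, and 2 and 1 without EG replicate 1 and 2. The Day6 count was at most 4 without any 1 array. With the block the Day3 count was 53 without E11.5 PGC replicate 1, 0 and 11 without Day3 replicate 1 and 2, and 14 and 11 without EG replicate 1 and 2. The Day6 count with the block was 107 without E11.5 PGC replicate 1, 3 without either Day3 array, 0 without either Day6 array, and 5 and 10 without EG replicate 1 and 2.

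On a scale where E11.5 PGC is 0 and EG is 1, Day3 lay at 0.526 ± 0.0237 (SD, n = 2) and Day6 at 0.810 ± 0.159 over all probes measured on all arrays. The values for replicates 1 and 2 were 0.543 and 0.509 at Day3 and 0.922 and 0.697 at Day6. Before the division by the EG slope those of Day6 were 0.606 and 0.640, in the other order. Both replicates share the same E11.5 PGC and EG arrays, so the SD is not a spread of independent replicates. Both Day6 arrays lay beyond both Day3 arrays, and no test was run on 2 arrays per group. The values of both replicates use the change from E11.5 PGC replicate 2 to EG replicate 2, which crosses the series because EG has no array in B. The scale leaves out differences in directions other than that from E11.5 PGC to EG. Across probes, the SD of log2 differences from EG replicate 1 was 1.044 for E11.5 PGC replicate 1. It was 0.833 for Day3 replicate 1 and 0.777 for Day6 replicate 1. For replicate 2 of these groups it was 1.196, 0.978 and 0.952. By this measure Day6 was only slightly nearer to EG than Day3.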

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

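The fit on series A arrays alone and the blocked models with a second setting were chosen after the data were seen. The count of called probes depends on how the array series, the dim probes and the variance are treated. With the replicate number as a block the counts were 804 for Day3 over E11.5 PGC, 78 for Day6 over Day3, 241 for EG over Day6 and 3951 for EG over E11.5 PGC, and 74 and 102 transient probes at Day3 and Day6; the labels do not say that arrays with the same number belong together. With the array series as a block the counts were 1725, 361, 395 and 4905, with 153 and 186 transient probes. The pseudocount gave 672, 62 and 151 in the first 3 comparisons, and 56 and 63 transient probes. Trend and robust variance gave 34 for Day6 over Day3, 98 for EG over Day6, and 39 and 47 transient probes. Removal of the dimmest probes gave 89 for EG over Day6 and 37 transient probes at Day6. The arrays of the compared groups alone gave 67 for Day3 over E11.5 PGC, 0 for EG over Day6 and 3804 for EG over E11.5 PGC, and 10 and 0 transient probes, with fewer arrays to estimate the spread. Series A alone gave 0 for EG over Day6, 3862 for EG over E11.5 PGC, and 77 and 0 transient probes. The fits on the compared groups alone and on series A alone also hold fewer samples. The cause of the change in count was not tested for any of these settings. Quantile normalization kept the counts within 1.5 times (2265 for EG over E11.5 PGC) but changed the split from 1157 higher and 1164 lower to 1315 and 950; with the block it moved the median change of all probes by 0.116 for EG over Day6 and 0.119 for EG over E11.5 PGC, and centring moved it by -0.115 for EG over Day6.

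Without 1 array the counts ranged from 4 to 555 for Day3 over E11.5 PGC, from 0 to 6 for EG over Day6, from 232 to 2809 for EG over E11.5 PGC, and were 0 each time for Day6 over Day3; they ranged from 0 to 46 for transient probes at Day3 and from 0 to 4 at Day6. With the block the ranges were 93 to 1822, 0 to 248, 0 to 404 and 1543 to 5001, with 0 to 166 transient probes at Day3 and 0 to 183 at Day6. With the block, missing values at the lowest value of the array gave 123 transient probes at Day6. The position of Day3 and Day6 moved by less than 1 SD in every setting tried for it. Of 367 changes of named genes, 147 were called and 0 reversed. A change counted as reversed only if its sign flipped and it was called in the model without a block or under that setting. Flips of sign without a call were not counted. The blocked models with a second setting or without 1 array were not part of this check. Of the 147, 94 stayed called in every other setting that gave them a value, apart from series A alone and the fits without 1 array. These settings include the arrays of the compared groups alone, which ended 40 of the calls. Leaving out any 1 array ended some of the 147 calls. Of the 92 list tests 25 were called by camera with the preset correlation, 0 with an estimated correlation and 14 by fry; with the array series as a block 0 were called with an estimated correlation and 11 by fry. Dim probes limit the reach of the tables: probes with a missing value had a median intensity of 1.80, where sizes of change are not exact.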

Other observations

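The genes in this paragraph were chosen after their values were seen, and so was the comparison of Day6 with E11.5 PGC. Of genes known to respond to BMP or Notch signals, not tested as a list, Id3 fell from E11.5 PGC to EG by 4.46 ± 0.59 (standard error, n = 2 arrays per group), the Notch target Hey1 by 4.71 ± 0.37, Msx2 by 5.11 ± 0.60 and the BMP inhibitor gene Smad6 by 1.57 ± 0.33. Id1 changed by -1.69 ± 1.59 and Msx1 by -1.62 ± 0.69 without a call. Tdpoz3, which like Zscan4c and Obox1 is known from early cleavage embryos, rose by 3.75 ± 0.55 from a level near the floor, so the size is not exact. Zscan4c had log2 intensities of 5.51 and 6.65 on the Day6 arrays and 10.42 and 12.05 on the EG arrays.

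Between Day6 and E11.5 PGC limma called 1734 probes (4790 with the array series and 2850 with the replicate number as a block). The count was 486 and 430 without E11.5 PGC replicate 1 and 2, 932 without Day6 replicate 1, 899 without either EG array, and 578 with the 4 arrays of these groups alone. With the block it was 2241 and 2934 without E11.5 PGC replicate 1 and 2, and 2106 without Day6 replicate 1. The highest changes were those of Bcat1 (6.65), Slc6a8 (6.55), Fgf4 (6.53), Upp1 (6.42) and Dnmt3l (6.29), and the lowest those of Lhx1 (-6.66), Esrp1 (-6.33), Umodl1 (-6.08) and Isl2 (-5.70). Fgf4 and Dnmt3l lay near the floor in E11.5 PGC and Umodl1 at Day6, so their sizes and ranks are not exact. Of the marker genes, Dnmt3b rose by 4.02 ± 0.41 and Klf4 by 3.96 ± 0.32 in this comparison. Nanog rose by 1.95 ± 0.46 and Zfp42 by 1.83 ± 0.30. Dusp6, a MEK/ERK target, fell by 4.64 ± 1.07, Dppa3 by 3.11 ± 0.67 and Ddx4 by 1.60 ± 0.31. The others measured gave no call. Nanog, the gene of the reporter, had the highest adjusted p of these calls (0.0464). The labels do not give the gate of the sort. Geometric mean intensities of Dusp6 were 333 in E11.5 PGC, 39.8 at Day3, 13.4 at Day6 and 119 in EG. Some transcripts had a value on both arrays of one group and on neither of the other, so no fold is given. In EG, Prl2c5 had a geometric mean intensity of 207 and Zfp57 one of 26.5, with no value in E11.5 PGC, where Isl2 had one of 172 with no value in EG. The stem cell factor gene Kitl had one of 13.2 at Day6 and no value in EG.

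All tests in the paragraphs that follow were chosen after the result was seen. Same-numbered arrays of E11.5 PGC, Day3 and Day6 deviated together from their group means. A number that marks a shared harvest in all 4 groups is argued against by EG, whose highest correlation with another group was 0.061. A difference between the 2 array series is consistent with the values, since the lowest correlation among the groups with 1 array in each series was 0.547. A shared harvest or day in those 3 groups alone was not tested and cannot be told from the array series, which follows the same numbers there.

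The list of CDK inhibitors and p53 targets had a median above 0 over E11.5 PGC at Day3 and in EG (camera adjusted p = 0.416 with an estimated correlation in both). Of its members 4 of 16 and 5 of 15 rose, Phlda3, Ccng1, Zmat3 and Fas both times, and Cdkn1c fell in EG. A difference between array series is argued against as the cause, since the lower of the within-series list medians at Day3 was 1.15 and the median in EG within series A was 0.87. Handling or sorting stress stays open at Day3, where immediate early/stress genes had a median of 0.42, below the 1.23 of the p53 list by more than 1 but less than 2 SD of their members (SD 0.75; the limit was widened from 1 to 2 SD after the values were seen), and in EG, where their median of -0.048 was below 1.22 by less than 1 SD (1.34), with Ddit3 above and Fos below 0. Fibroblast or mesenchymal cells also stay open, with list medians of 0.26 at Day3 (SD 1.24) and 0.072 in EG (SD 2.05). The labels say that candidate pluripotent cells were purified by flow sorting, which would be aimed at removing such cells. They do not give the gate or say which groups were sorted. With members spread this widely, a stress or fibroblast list with a median of 0 would also have stayed open under the 2 SD limit. These comparisons therefore could not decide either question. A response of the cells themselves to culture was not tested apart from these.

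Over the target lists of MEK/ERK and of TGF-beta/Activin signalling, neither of them called, changes from E11.5 PGC to Day3 had a negative rank correlation with those from Day6 to EG: over 29 genes it was -0.551, under that of all but 0.92% of 10000 random lists (median -0.108; genes are not independent replicates), and 18 genes, Lefty1 among them, had opposite signs, as did 10 of 14 LIF/STAT3 targets. An array series difference is argued against, since within series A the correlation was -0.687, against a median of -0.236 for random lists there. Weaker inhibition of these pathways in the EG cells stays open, since a negative correlation does not show that the targets rose: from Day6 to EG the median of MEK/ERK targets was 0.29, but -0.16 with the array series as a block and -0.40 within series A, with 9 of 16 of opposite sign, and that of TGF-beta/Activin targets 0.37, 0.28 and 0.12. A wider pattern of signalling genes stays open as well: the higher of the correlations for the Wnt and LIF/STAT3 target lists was -0.538, near that of these lists, but 8.72% and 5.84% of random lists were at or under theirs, and within series A they were -0.245, which is the median of random lists, and -0.512. What these explanations need was made stricter after the values were seen, and the labels do not say when the EG cells last met the inhibitors. A part of fibroblast or mesenchymal cells in this pattern was not tested. The median of their list was 0.26 from E11.5 PGC to Day3 and -0.50 from Day6 to EG. Within series A these medians were 0.79 and -1.77. Tagln stands in both that list and the TGF-beta/Activin list.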
